A study of Mus musculus with 6 samples.

How the data were processed

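Ovarian tumours of mice that express the B form of the progesterone receptor were profiled on 6 single-colour (Cy3) Agilent arrays, 3 from mice given a placebo pellet and 3 from mice given a slow-release pellet of RU486. RU486 (mifepristone) is a steroid that blocks the progesterone receptor and the glucocorticoid receptor. Per the labels, pellets were in place for 24 h and tumours measured 0.5 to 1 cm across. Groups and replicate numbers were taken from the sample titles. The labels do not say whether every array holds a different mouse, so p-values of single genes measure the spread between these samples.

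The deposited values are scores: each of the 37932 probes was centred and scaled over the 6 arrays, so that every probe has a mean of 0 and an SD of 1 within rounding. This was found from the values, the largest of which is 2.04, the limit that a z-score of 6 values can reach. Brightness and fold change can therefore not be recovered, and levels of different probes cannot be compared. Per the submitters' processing notes Partek was used, with no version. Background correction, normalization, any probe filter, whether log or linear intensities were scaled, and the direction of the scale are not given in the sources used here. A higher score was taken as a brighter probe. Of the probes, 68.8% had a score distribution skewed to the right. Signal over background is unknown for these arrays, and their number limits the precision. Median scores were -0.384, -0.0677 and 0.212 in placebo arrays 1 to 3, and -0.363, -0.0875 and -0.154 in RU486 arrays 1 to 3. No 2 arrays held identical values (0 pairs). Centring every probe forces the mean correlation between arrays to about -0.2, so array correlations were not read as similarity.

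Probes were named from the platform annotation: 24903 had 1 gene symbol, 0 had several and 13029 had none listed. The Entrez ID of 24627 named probes matched the RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. That table served for symbols and, through its gene positions, for which genes neighbour each other and lie within 10 kb; no coordinates are printed, since the files name no build. The scores of a gene's probes were averaged, which gave 21878 genes, of which 19235 had 1 probe and 2643 had 2 or more.

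The difference given for a gene is the RU486 mean minus the placebo mean of its score, called the standardised difference. For a gene with 1 probe it is in units of that probe's SD over the 6 arrays. For a gene with more probes it is the mean of their differences, with no further scaling, and is smaller where the probes disagree. Its size cannot pass 1.83. Each gene was fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays with treatment as the term. The ordinary statistic with 4 residual degrees of freedom was used, since it has the same value before and after a probe is scaled. This does not hold for a gene with more probes, whose scores were scaled before they were averaged. The 1-step moderation of limma (eBayes) was fixed for log2 values, and scaled probes give it an infinite prior and a smallest possible p of 0.018, so it was kept as an alternative. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The planned filter on low values, the choice of the brightest probe of a gene, the 1.5-fold limit and the intensity trend could not be applied to scaled values, and only the unadjusted p of 0.01 was kept from the descriptive count.

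Before the data were examined, 42 gene lists and the rule for named genes were fixed. The lists cover the cell cycle, targets of steroid receptors, ovarian and other cell types, metabolism and stress. The 2 cell cycle lists were made the main lists because the title of the series names a signature of proliferation, so that choice was not blind. Of these, 41 had at least 5 measured genes; the core histone list had fewer and was not tested. Lists were tested with limma's camera on z-transformed ordinary statistics, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 41 lists. Camera with a correlation estimated from the residuals, and fry, which asks whether a list's genes move on balance one way, were run beside it. Camera sets the genes of a list against the other genes. With the preset correlation its p-values therefore do not measure the spread between arrays, and they are too small where genes of a list move together. A list mean is the mean score of its genes on one array, and list means of the groups were compared by an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1. Named genes are the genes at an adjusted p under 0.05 with separated groups (at most 10 per direction), the 5 genes of smallest unadjusted p in a direction where none passed, the 4 members of smallest unadjusted p in each list past the test and in the receptor target lists, and a fixed panel. Ccnb1, Areg and Cyp19a1 of the panel were not matched and are not analysed here. Some items that the rule names are not reported here.

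The fit was tested on simulated data: 50 of the 21878 genes were changed at each of 4 sizes. The ordinary statistic called 100% of those changed by 32 within-group SDs, 96% at 16, 28% at 8 and 8% at 4, with 5 false calls in all, and the moderated test called 0% of them. Simulated lists of 20 genes with no shift reached p under 0.05 in 3% of cases with uncorrelated genes. With a correlation of 0.5 that share was 49.5% with the preset correlation, 8% with the estimated one and 5% with fry. Of lists shifted by 1.5 SD at that correlation, 90% were found with the preset correlation, 38.5% with the estimated one and 53% with fry. Alternatives were another normalization of the scores (quantile, or each array centred on its median), array weights, separate probes or the first probe of a gene, a replicate block, the other set tests and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.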

Results

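Tumour RNA from 3 placebo and 3 RU486 arrays was compared to ask which transcripts differ after 24 h with an RU486 pellet, with genes of proliferation as the main interest. Values are scores scaled per probe over the 6 arrays, so each difference below is a standardised difference, RU486 minus placebo, in SDs of a probe over the 6 arrays, averaged over the probes of a gene, with a limit of 1.83 in size. It is not a fold change, and where the probes of a gene disagree their average is smaller. In all, 21878 genes were tested.

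Genes of mitosis and of DNA replication were lower in the RU486 tumours as lists, with camera adjusted p of 8.04e-24 and 5.53e-17. With the estimated correlation between genes the adjusted p = 0.158 for both, and single genes rarely passed a test over all genes. With limma's ordinary statistic 1 gene passed an adjusted p of 0.05, and 0 genes were higher. It was Cep295nl (Entrez gene 58251), a CEP295 N-terminal-like gene, with a difference of -1.83 (SE 0.0112, adjusted p = 0.000187). Its placebo scores averaged 0.913 ± 0.00866 and its RU486 scores -0.913 ± 0.0174 (SD, n = 3). In limma the call was lost after each array was centred on its median (adjusted p = 0.162) and after quantile normalization (adjusted p = 0.107). With eBayes moderation the adjusted p = 0.364. Its smallest possible p on scaled values is 0.018, so a gene could pass there only if a large share of all genes came near that value. Over the other alternatives without a block the adjusted p ranged from 0.000144 with array weights to 0.024 without placebo array 1. With the replicate block the call was lost too, and 0 genes passed. At an unadjusted p of 0.05 there were 2695 genes, 1548 lower and 1147 higher, where chance gives 1094 on average. At an unadjusted p of 0.01 there were 711 genes, where chance gives 219 on average, and 571 of them (80.3%) were lower with RU486. The balance turned without RU486 array 2, with 848 genes of which 44.2% were lower, and with array weights, with 2579 genes of which 38.8% were lower. The count was 385 without RU486 array 1, 441 without RU486 array 3, 432 without placebo array 2 and 440 without placebo array 3. The chance averages do not give the spread of a count when genes move together. Other splits of the same arrays, which mix the treatments, gave from 45 to 1291 genes at an unadjusted p of 0.01. Of 10 splits, the real one included, 2 gave a count as large as 711, so the excess over chance does not by itself show a treatment effect. The groups did not overlap in 4806 genes (22.0%, where chance gives 10%), of which 2365 were lower and 2441 higher. The 5 genes of smallest unadjusted p among those with higher scores did not pass, with adjusted p from 0.133 to 0.165 in limma. They were Scx, a transcription factor of tendon cells, at 1.81, Lppos at 1.81, the ubiquitin ligase gene Rnf125 at 1.81, Tcstv1 at 1.80 and the transcription factor gene Onecut1 at 1.00. The 2 Onecut1 probes alone had unadjusted p of 0.373 and 0.162.

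The list of mitosis and G2/M genes fell with RU486. Its median difference was -1.68 over 41 genes, 40 of them lower, and camera gave an adjusted p of 8.04e-24 with the preset correlation. With the estimated correlation of 0.70 between its genes the adjusted p = 0.158. List means were 0.79 ± 0.46 in placebo and -0.79 ± 0.25 in RU486 arrays (SD, n = 3), with the 3 RU486 arrays below the 3 placebo arrays (exact permutation p = 0.1, the smallest possible). When adjusted over the list alone, 37 genes fell, 0 rose and 4 did not pass. Over all genes 0 passed in limma, with 37 lower and 1 higher at an unadjusted p of 0.05. They included Nusap1 (-1.80, SE 0.157), a spindle protein gene, Cdca3 (-1.75, SE 0.253), Ube2c (-1.74, SE 0.283), which codes for the E2 enzyme of the anaphase-promoting complex, and Anln (-1.73, SE 0.288), a gene of cytokinesis. Of the 4 that did not pass, Aurkb, a mitotic kinase gene, had a higher score with RU486, at 1.49. Without RU486 array 1 or RU486 array 3 the count adjusted over the list alone was 0, and without placebo array 2 it was 25, while 40 of 41 differences were negative in each case. Markers of neutrophils, of B and plasma cells and of skeletal muscle parted the arrays the same way but by smaller gaps between list means. Their medians were -0.77, -0.65 and -0.79, and these lists did not pass the set test.

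Genes of DNA replication and the G1/S step fell likewise, with a median difference of -1.66 over 39 genes and a camera adjusted p of 5.53e-17. With the estimated correlation the adjusted p = 0.158. List means were 0.68 ± 0.46 in placebo and -0.68 ± 0.19 in RU486 arrays (SD, n = 3). Of its genes, 27 fell, 1 rose and 11 did not pass, adjusted over the list alone. Among those that fell were Orc6 (-1.80, SE 0.155) of the origin recognition complex, Mcm5 (-1.76, SE 0.249) of the replicative helicase, Pole (-1.71, SE 0.274), a DNA polymerase gene, and Gins2 (-1.73, SE 0.288), which codes for a partner of that helicase. The 1 gene that rose was Ccne2, a cyclin E gene, at 1.69 (SE 0.342). Its relative Ccne1 stood at -1.68 (SE 0.361) and fell in the same list. The count of 27 was 0 without placebo array 2, RU486 array 1, RU486 array 2 or RU486 array 3, with at least 36 of 39 differences negative.

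The list of homologous recombination and Fanconi genes, which repair broken and crosslinked DNA, also fell. All 18 differences were negative, with a median of -1.65 and a camera adjusted p of 2.7e-11. With the estimated correlation the adjusted p = 0.092. Of these, 12 fell, 0 rose and 6 did not pass, adjusted over the list alone. The nuclease genes Eme1 (-1.76, SE 0.237) and Exo1 (-1.71, SE 0.316) and the helicase gene Blm (-1.74, SE 0.279) were among them. That count was 0 without placebo array 2, RU486 array 1 or RU486 array 3, 6 without placebo array 3 and 7 without RU486 array 2. List means of repair genes were 0.41, 0.57 and 1.26 in placebo arrays 1 to 3 and -0.79, -0.54 and -0.91 in RU486 arrays 1 to 3. The mitosis list had 0.46, 0.59 and 1.31, and -0.81, -0.53 and -1.03. Whether repair genes fell apart from the cell cycle was not tested.

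**Figure D1:**
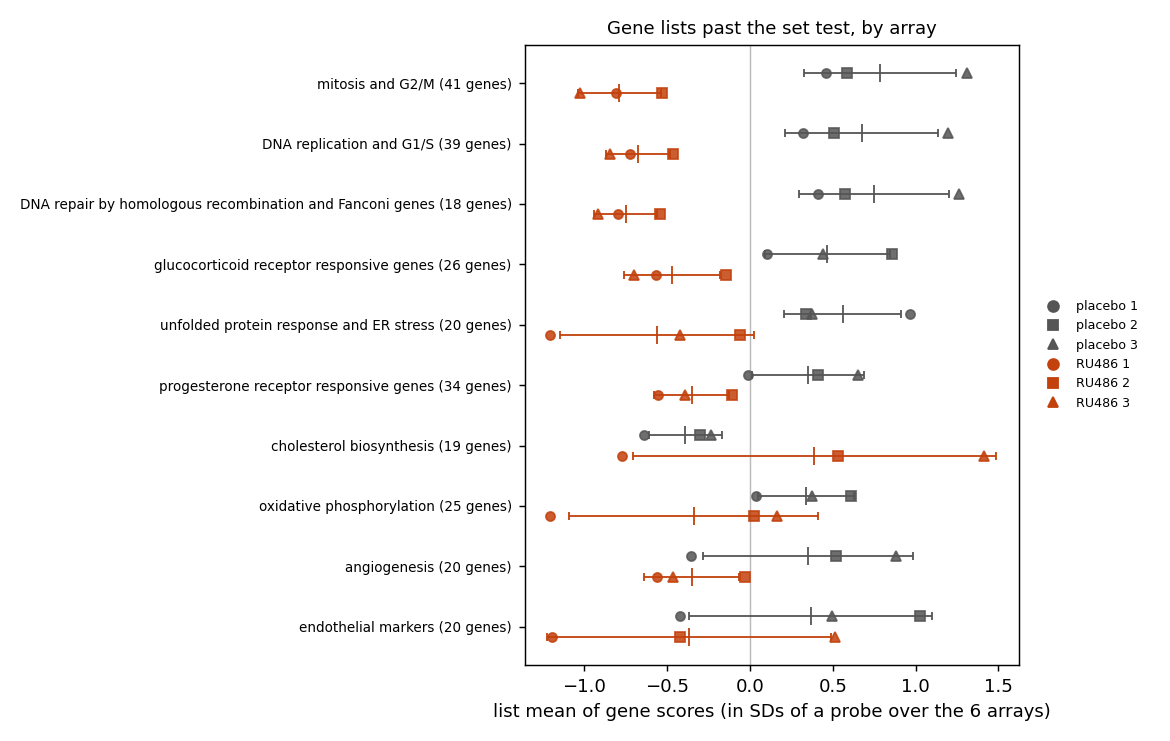
List means of gene scores (x axis, in SDs of a probe over the 6 arrays) for the 10 lists past the set test, with 1 point per array, a vertical tick at the group mean and bars of 1 SD (n = 3). The 3 RU486 arrays lie below the 3 placebo arrays in the first 6 lists, while the groups overlap in the last 4; RU486 array 3 stands at 1.41 in the cholesterol list.

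Proliferation genes of the fixed panel had large negative differences with separated groups, and none passed over all genes. Mki67, the gene of the Ki-67 antigen, stood at -1.68 (SE 0.363, limma adjusted p = 0.306), Cdk1 at -1.73 (SE 0.297), Top2a at -1.59 (SE 0.444), and the transcription factor gene E2f1 at -1.69 (SE 0.344). Ccnd1, the cyclin D1 gene, stood at -1.75 (SE 0.268). In the list of growth factor and early mitogenic genes, adjusted over the list alone, Ccnd1 and the growth factor gene Hbegf (-1.77, SE 0.216) fell, and 24 of the 26 genes did not pass. The 2 that fell became 1 without placebo array 1 or placebo array 2, and 0 without placebo array 3 or any of the 3 RU486 arrays. With array weights 3 fell and 1 rose, and 1 rose without RU486 array 3. That list did not pass the set test (adjusted p = 0.109). Ccnd2 (-0.13, SE 0.91), Myc (-0.23, SE 0.906), and the CDK inhibitor genes Cdkn1b (1.12, SE 0.717) and Cdkn1c (0.40, SE 0.891) had overlapping groups. For Cdkn1a, another CDK inhibitor gene, the mean was 0.52 (SE 0.744) and its 3 probes disagreed, at -0.39, 0.79 and 1.17. Left out in turn, single arrays turned the sign of Ccnd2, Myc and Cdkn1c.

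Genes that glucocorticoid receptor activation is known to induce fell with RU486, and of the 10 lists this one held with either correlation. Its median difference was -1.21 over 26 genes, 21 of them lower, with a camera adjusted p of 2.68e-06 and, with the estimated correlation, an adjusted p = 0.0265. With fry, which compares no other genes, the adjusted p was 0.223. The median was -0.77 without placebo array 2. List means were 0.47 ± 0.38 in placebo and -0.47 ± 0.29 in RU486 arrays (SD, n = 3). Of its genes, 10 fell, 0 rose and 16 did not pass, adjusted over the list alone. Those that fell included Cebpd (-1.80, SE 0.15), a transcription factor gene, Hif3a (-1.78, SE 0.213), Arrdc2 (-1.77, SE 0.231) and Lcn2 (-1.76, SE 0.234), the lipocalin 2 gene, which the neutrophil list also holds. Leaving out placebo array 1 or placebo array 2 left 2 such genes, leaving out placebo array 3 left 0, and leaving out RU486 array 1 left 5. Without RU486 array 3, 7 fell and 1 rose. Panel genes induced by glucocorticoids stood at -1.60 (SE 0.438) for Zbtb16, with separated groups, and at -1.15 (SE 0.71) for Tsc22d3, -1.10 (SE 0.729) for Fkbp5 and -0.74 (SE 0.773) for Per1, with overlapping groups.

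The list of progesterone receptor responsive genes fell as well, with a median of -0.77 over 34 genes, 26 of them lower. That median was -1.27 without placebo array 1, -0.49 without placebo array 3 and -1.30 with array weights. The camera adjusted p was 0.000284, and with the estimated correlation the adjusted p = 0.092. List means were 0.35 ± 0.34 in placebo and -0.35 ± 0.22 in RU486 arrays (SD, n = 3). In it 6 genes fell, 0 rose and 28 did not pass, adjusted over the list alone. Mmp19 (-1.81, SE 0.132), a matrix metalloproteinase gene, Klf15 (-1.79, SE 0.181), Hand2 (-1.78, SE 0.213), a transcription factor gene that progesterone induces in uterine stroma, and Lrp2 (-1.70, SE 0.212) were the first 4, and Sgk1 and Errfi1 belong to the glucocorticoid list too. That count was 2 without placebo array 1, 1 without placebo array 3, 3 without RU486 array 1 or RU486 array 3, and 0 without RU486 array 2, while with array weights 11 fell and 1 rose. Tnfsf11, the RANKL gene that progesterone induces in breast, went the other way, at 1.64 (SE 0.404) with separated groups, and did not pass. Wnt4, another target in that tissue, stood at -1.05 (SE 0.699) with overlapping groups.

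**Figure D2:**
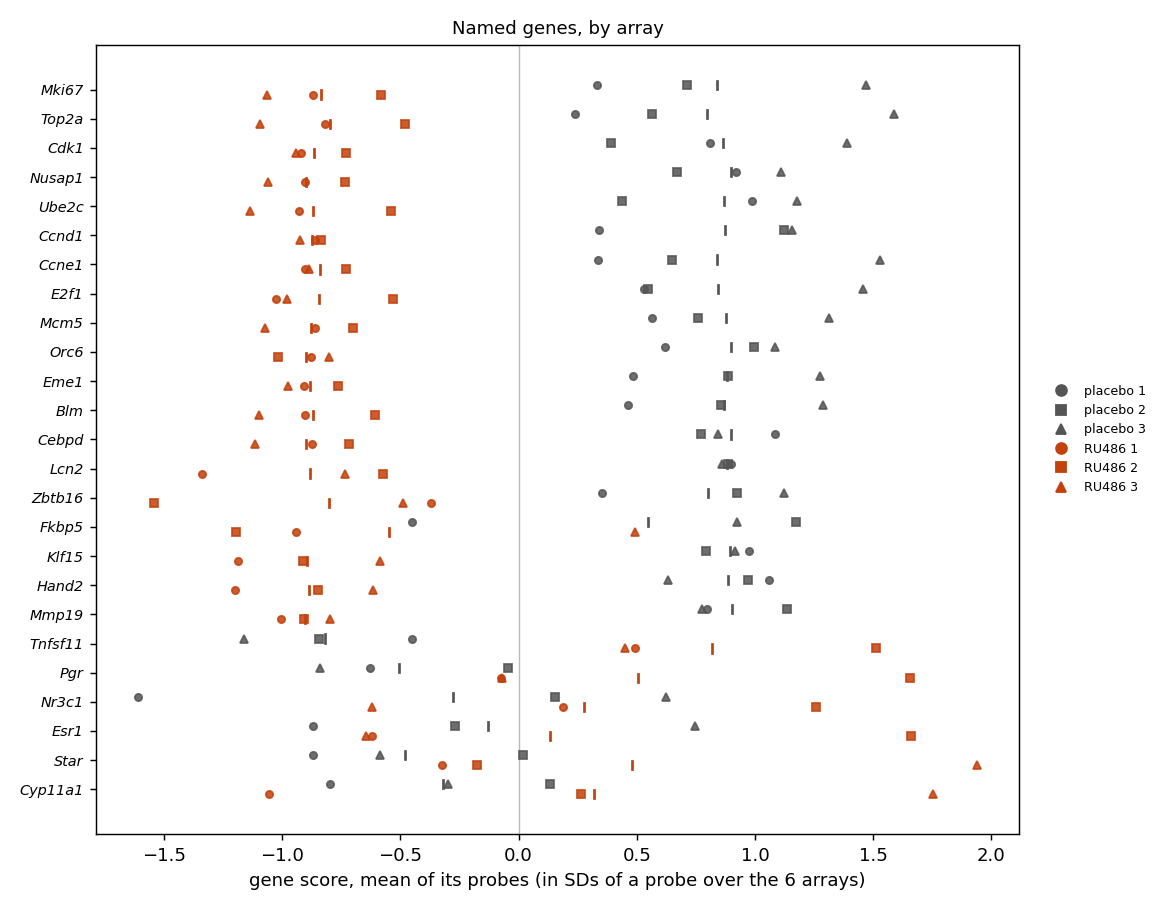
Scores of 25 named genes on each array (x axis, in SDs of a probe over the 6 arrays), with 1 point per array and a vertical tick at each group mean. The groups are separated from Mki67 to Zbtb16 and from Klf15 to Tnfsf11, with Tnfsf11 higher in RU486 arrays, and overlap in Fkbp5, Pgr, Nr3c1, Esr1, Star and Cyp11a1.

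The receptor genes themselves showed no call. Pgr, whose probes are not known to tell the B form from the A form, had scores of -0.628, -0.0443 and -0.84 in placebo arrays 1 to 3 and -0.0751, 1.66 and -0.0681 in RU486 arrays 1 to 3. The mean difference was 1.01 (SE 0.623, limma adjusted p = 0.582), with 1.60 at one probe and 0.42 at the other. The glucocorticoid receptor gene Nr3c1 stood at 0.55 (SE 0.87), Esr1 at 0.26 (SE 0.898) and Esr2 at -1.20 (SE 0.688), each with overlapping groups, and Nr3c1 and Esr1 changed sign with array weights and without placebo array 1, and Esr1 without RU486 array 2 as well. The list of steroid receptors and coregulators did not pass (adjusted p = 0.584).

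Genes of protein folding, of respiration and of vessels were also lower as lists, and none of these lists held with the estimated correlation. The unfolded protein response list had a median of -1.34 over 20 genes (camera adjusted p = 3.49e-05; with the estimated correlation the adjusted p = 0.316). In it 0 genes passed when adjusted over the list alone, and 6 were lower at an unadjusted p of 0.05; without RU486 array 2 or with array weights 1 passed. The endoplasmic reticulum chaperone genes Hyou1 and Calr stood at -1.65 (SE 0.386) and -1.59 (SE 0.447), Herpud1 at -1.64 (SE 0.4) and Sel1l at -1.60 (SE 0.443). Oxidative phosphorylation genes had a median of -0.73 over 25 genes (camera adjusted p = 0.02; with the estimated correlation the adjusted p = 0.862). Cycs, the cytochrome c gene, stood at -1.62 (SE 0.417), Atp5o at -1.55 (SE 0.482), Ndufa4 at -1.51 (SE 0.514) and Cox5a at -1.43 (SE 0.565). Again 0 passed over the list alone, and 3 were lower at an unadjusted p of 0.05. RU486 array 1 had the lowest list mean, at -1.20, and without it the adjusted p was 0.179 and the median -0.41. It was 0.0504 without placebo array 1 and 0.0585 without placebo array 2, and at its lowest 0.000636 without RU486 array 3, with a median of -1.16. With array weights the median was -1.12.

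Angiogenesis genes had a median of -0.97 over 20 genes (camera adjusted p = 0.0247; with the estimated correlation the adjusted p = 0.77), and 0 passed over the list alone, with 4 lower and 1 higher at an unadjusted p of 0.05. With array weights 5 fell and 1 rose over the list alone, and without placebo array 1, 1 fell. The protease gene Adamts1 stood at -1.65 (SE 0.387), the Notch ligand gene Dll4 at -1.62 (SE 0.421) and Esm1 at -1.58 (SE 0.455), whereas Pdgfb stood at 1.59 (SE 0.45). Endothelial markers had a median of -0.94 over 20 genes (camera adjusted p = 0.034; with the estimated correlation the adjusted p = 0.898), and list means of the groups overlapped. Vwf stood at -1.50 (SE 0.482), Kdr at -1.28 (SE 0.65), Robo4 at -1.25 (SE 0.668) and Emcn at -1.21 (SE 0.682), and 0 passed over the list alone, with 1 lower at an unadjusted p of 0.05. The angiogenesis list did not pass without RU486 array 2 (adjusted p = 0.0784), without RU486 array 3 (0.0665) or with array weights (0.0522), and its adjusted p was lowest without placebo array 1 (0.00933). The endothelial list did not pass without RU486 array 1 (0.222, median -0.41), RU486 array 2 (0.153) or placebo array 2 (0.171, median -0.50), or with the first probe of each gene (0.0505), and its adjusted p was lowest without RU486 array 3 (6.64e-05).

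Cholesterol biosynthesis was the 1 list that was higher with RU486, with a median of 0.95 over 19 genes, 18 of them higher (camera adjusted p = 0.0158; with the estimated correlation the adjusted p = 0.898). When adjusted over the list alone 0 genes passed, and at an unadjusted p of 0.05 there was 1, the sterol isomerase gene Ebp, which was lower at -1.54 (SE 0.488). Fdft1, the squalene synthase gene, stood at 1.42 (SE 0.571), Sqle, the squalene epoxidase gene, at 1.36 (SE 0.61) and Hmgcs1 at 1.30 (SE 0.528). List means were 1.41 in RU486 array 3, 0.529 in RU486 array 2 and -0.77 in RU486 array 1, the last below the placebo arrays. Without RU486 array 3 the adjusted p was 0.327 and the median 0.30, without RU486 array 2 it was 0.0718, and with array weights it was 0.0518. Without RU486 array 1 it was 9.01e-08, with a median of 1.52 and 5 genes that rose over the list alone.

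Steroidogenic genes did not pass as a list (median 0.31 over 18 genes, adjusted p = 0.466), with 0 genes at an unadjusted p of 0.05. Star, which moves cholesterol into mitochondria, stood at 0.96 (SE 0.777) and Cyp11a1, which opens steroid synthesis, at 0.64 (SE 0.855), and both had their highest score on RU486 array 3, at 1.94 and 1.75. The progesterone-degrading enzyme gene Akr1c18 stood at 0.69 (SE 0.844), with 2.03 on RU486 array 1 and negative scores on the other 5 arrays. Without those arrays the sign of Cyp11a1 or of Akr1c18 turned. The granulosa cell genes Inha (0.34, SE 0.897) and Foxl2 (-1.06, SE 0.745) had overlapping groups, and the sign of Inha turned with array weights and without RU486 array 2 or placebo array 1.

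Among markers of the cell types a tumour piece can hold, the endothelial list alone passed (adjusted p = 0.034), and with the estimated correlation the adjusted p = 0.898. It did not pass without RU486 array 1, RU486 array 2 or placebo array 2. Neutrophil (median -0.77, adjusted p = 0.0674), B and plasma cell (-0.65, adjusted p = 0.199) and skeletal muscle markers (-0.79, adjusted p = 0.121) had list means lower in the 3 RU486 arrays than in the 3 placebo arrays, as the cell cycle and receptor target lists did. The gaps differed in size. Placebo array 2 and RU486 array 2 stood at 0.044 and 0.014 for neutrophil markers, and at 0.017 and -0.037 for B and plasma cell markers. For skeletal muscle markers the nearest were placebo array 2 at 0.128 and RU486 array 1 at -0.14. In the mitosis list they were placebo array 1 at 0.461 and RU486 array 2 at -0.528, and in the progesterone receptor list the same arrays at -0.0097 and -0.109. The groups overlapped in markers of macrophages (adjusted p = 0.554), T and NK cells (0.246), lymphatic endothelium (0.776), smooth muscle and pericytes (0.0979), fibroblasts and matrix (0.114), adipocytes (0.812) and red cells (0.109). They also overlapped in markers of granulosa (0.735), theca (0.701) and luteal cells (0.854), oocytes (0.398) and ovarian surface epithelium (0.812). Among these lists the median and the mean differed in sign for granulosa (0.12 and -0.12), theca (-0.025 and 0.092) and epithelial markers (0.15 and -0.0070), and the test's direction differed from the median for granulosa, theca, luteal and lymphatic markers. Single arrays stood apart within groups: red cell markers averaged 1.64 on placebo array 1, and macrophage markers 1.15 on RU486 array 2. Although its list means overlapped, the red cell list had a median of -1.02. Of its 10 genes, 8 had separated groups with lower RU486 scores and 1 with higher ones.

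**Figure D3:**
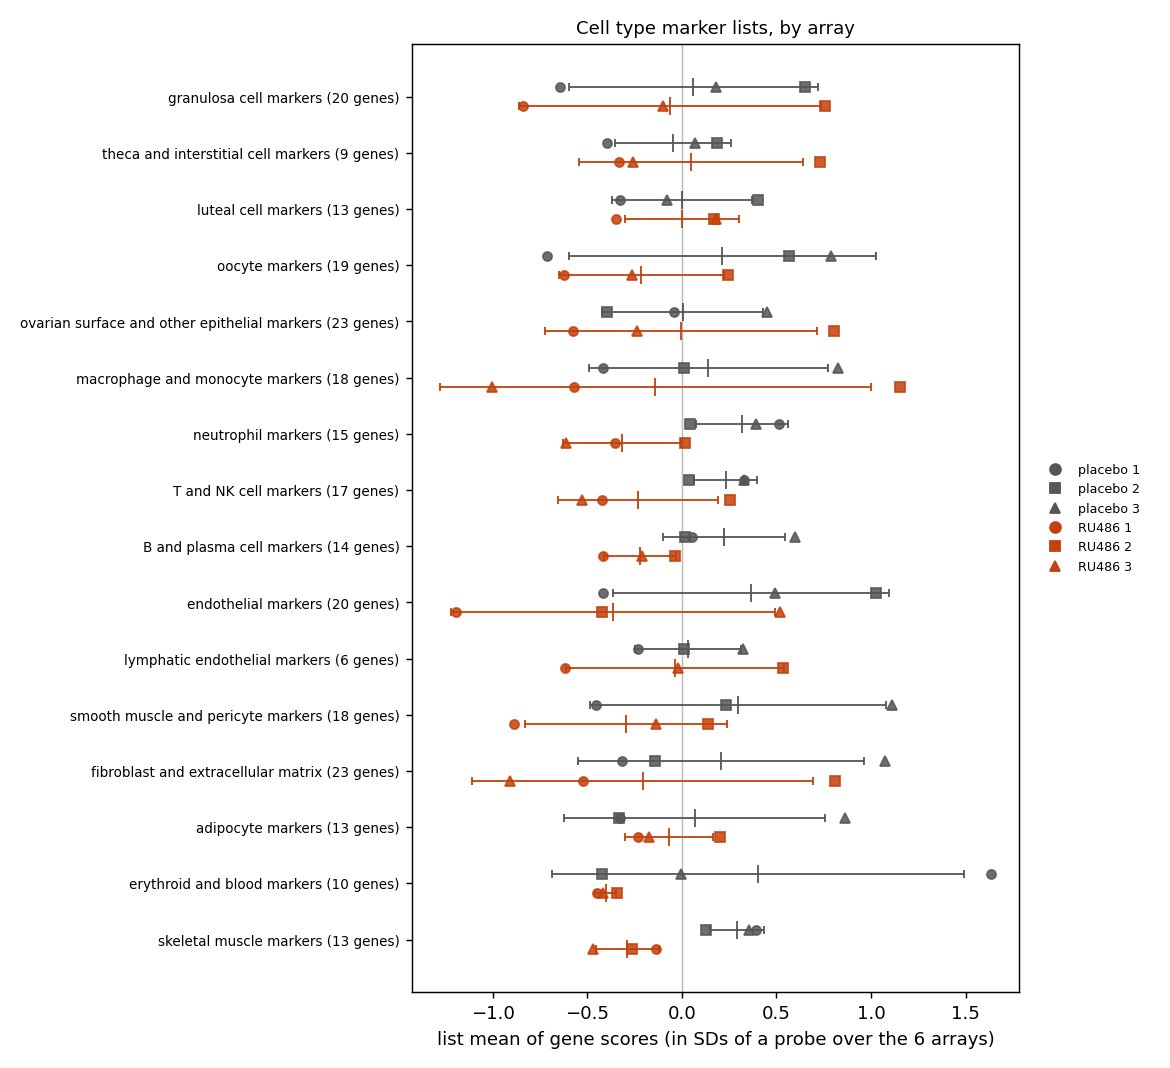
List means of gene scores (x axis, in SDs of a probe over the 6 arrays) for 16 cell type marker lists, with 1 point per array, a vertical tick at the group mean and bars of 1 SD (n = 3). The groups are separated in the neutrophil, B cell and skeletal muscle lists, and placebo array 1 stands at 1.64 in the red cell list.

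The remaining lists did not pass. Heat shock genes had list means lower in all 3 RU486 arrays (median -0.97, adjusted p = 0.102), but barely so, with placebo array 2 at -0.172 and RU486 array 2 at -0.178. The groups overlapped for ribosome biogenesis and MYC targets (adjusted p = 0.111), interferon response (0.111), fatty acid synthesis (0.219), MHC class II presentation (0.219), ribosomal proteins (0.352), complement and acute phase (0.412), p53 targets and CDK inhibitors (0.466), ovulation genes (0.508), immediate early genes (0.508), apoptosis (0.508), inflammatory cytokines (0.708) and hypoxia and glycolysis (0.744).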

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

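The plan fixed eBayes, its moderated statistics in camera and the brightest probe of a gene. The ordinary statistic and the averaging of probes replaced them once the values were found to be scaled. The first-probe and rank alternatives and the lists without cell cycle genes were also chosen after the data were seen. Where no cause is named below, the cause was not tested. The count of 1 gene past the adjusted threshold became 2 with separate probes (Cep295nl and Nalcn, the second named after its values were seen) and 7 with array weights. It became 0 after median centring, quantile normalization or eBayes, with 2171, 2279 and 2474 genes at an unadjusted p under 0.05, and 1 to 3 with 1 array left out. With eBayes, whose smallest possible p is 0.018, a gene could pass only if a large share of all genes came near that value. The 3 genes besides Cep295nl called without an RU486 array, named after their values were seen, were Usp17le-ps (without array 1), Ces2h and Olfr44 (without array 2), each higher. The count of 711 genes at an unadjusted p of 0.01 became 2579 with array weights (38.8% lower), 0 with eBayes, whose smallest possible p lies above 0.01, and 385 to 848 with 1 array left out. Of the 711, 480 had p under 0.01 after median centring too. The 10 lists became 1 with the estimated correlation and 0 with fry (over all 41 lists, 7 had an unadjusted p under 0.05, skeletal muscle markers among them, which are not one of the 10), and 8 to 14 with 1 array left out. The adjusted p of the mitosis list and of the replication list was 0.158 with the estimated correlation and 0.103 with fry. With 1 array left out it ranged from 5.47e-31 to 2.28e-14 for mitosis and from 1.15e-23 to 5.14e-10 for replication. Both lists also passed in the other alternatives run. Leaving cell cycle genes out of the other lists is no test of them, since it keeps both lists whole. With eBayes 36 mitosis genes and 0 replication, repair, glucocorticoid or progesterone receptor list genes passed over the list alone. Centring moved the median difference of all genes from -0.058 to 0.063, and array weights to -0.281. Among the 72 named genes, 0 changed sign after centring or quantile normalization, and Esr1, Inha and Nr3c1 did with array weights. Filters on low values, a 1.5-fold limit and an intensity trend were not run, since scaled scores hold no level, and signal over background is unknown.

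The labels do not say whether equal replicate numbers mark pairs, and the values cannot decide it. Deviations of same-numbered arrays correlated at 0.254, 0.0539 and -0.272, and those of other placebo and RU486 arrays at -0.36 to 0.357. With the number as a replicate block, 0 genes passed (1535 at an unadjusted p under 0.05), 311 had an unadjusted p under 0.01 (73.6% lower), 9 lists passed (oxidative phosphorylation did not, adjusted p = 0.0718), and over the list alone 0 mitosis, replication, repair and progesterone receptor list genes and 1 glucocorticoid list gene passed.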

Other observations

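The test of cell type markers and the counts of genes over splits of the arrays were chosen after the results they bear on were seen. Single members of lists that did not pass as a whole also fell when adjusted over their list alone; they were picked out after their values were seen. Rgs2, a regulator of G protein signalling in the luteal and ovulation lists, stood at -1.81 (SE 0.122), the interferon-induced Mx1 at -1.82 (SE 0.0891), the gelatinase gene Mmp2 at -1.79 (SE 0.167), the fibronectin gene Fn1 at -1.76 (SE 0.249), the smooth muscle myosin gene Myh11 at -1.78 (SE 0.209) and Bcl2l1, which codes for the survival protein BCL-XL, at -1.79 (SE 0.189). In limma their adjusted p over all genes lay between 0.0932 (Mx1) and 0.237 (Fn1), so none passed there. Lcn2 fell within the neutrophil list and the complement list, and it belongs to the glucocorticoid list as well. With 1 array left out, the luteal, ovulation and interferon lists each had at least 1 gene that fell. The count was 0 in the smooth muscle list when any array but RU486 array 2 was left out, in the neutrophil list when any array but RU486 array 1 was left out, in the complement list without any placebo array or RU486 array 3, in the matrix list (Mmp2 and Fn1) without placebo array 1, placebo array 3 or RU486 array 2, and in the apoptosis list (Bcl2l1) without placebo array 1, placebo array 3, RU486 array 1 or RU486 array 3. With eBayes it was 0 in all of these lists, but with a smallest possible p of 0.018 so few genes of a list could not pass. In the core histone list, which was too short to test, the chromatin protein genes Hmgb2 and Hmgn2 stood at -1.67 (SE 0.37) and -1.50 (SE 0.518). At an adjusted p under 0.10 there were 8 genes, all 8 lower: Cep295nl, Mx1, Phf11c, Setdb2, Nalcn, Abhd17b and the mitochondrial protein genes Slc25a5 and Higd1a.

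The 2 cell cycle lists lay lower in RU486 arrays. A shift of scores common to a whole array is too small to account for it. Centring each array moves all genes with 1 probe by the same amount, and the mitosis median went from -1.68 to -1.56. Brightness before scaling cannot be recovered from scores, so a difference in it is not excluded. Fewer cells of another type in the RU486 tumours stay open. Of 8 marker lists the neutrophil list mean differed by -0.635 (SE between arrays 0.23, or -2.76 SE against a limit of 2.78). The red cell list had the largest difference, at -0.806 (SE 0.629), and the endothelial one stood at -0.733 (SE 0.65). The red cell difference rests largely on placebo array 1, at 1.64. Placebo arrays 2 and 3 stood at -0.42 and -0.0052, and RU486 arrays from -0.45 to -0.34. Scaled scores hold no levels to set a share of cells against. An effect of RU486 on division of the tumour cells may account for the pattern but was not tested apart from treatment. The 10 splits of 6 arrays are too few for a share under 0.05: only the real split (1 of 10 for each list) reached the real median sizes of 1.68 for mitosis and 1.66 for replication, and the highest others were 0.973 and 0.931.

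The glucocorticoid list lay lower in RU486 arrays; RU486 also blocks that receptor, and this was not tested apart from treatment. The 5 members shared with the progesterone receptor list do not account for it, since the other 21 genes had a median of -1.19, with 16 of them lower. The 29 genes of the progesterone receptor list alone had a median of -0.64, so the removal does not tell the 2 receptors apart. Tissue handling or acute stress stays open although the bound set in advance was met: its first part rests on 1 gene, Dusp1, that could be left out, which could not change the list's test. In its second part the immediate early list did not pass (adjusted p = 0.508, 12 of 21 lower), which does not show that those genes did not differ. Lower hormone levels in the mice, or fewer cells that respond to glucocorticoids, stay open and were not tested.

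Genes at an unadjusted p of 0.01 lay next to each other more often than shuffled genes, with 37 neighbouring pairs changed the same way against 15.9 expected (permutation p = 1e-04, the smallest that 10000 shuffles can give). Overlapping genes, close promoters and paralogs may explain much of it, since without pairs within 10 kb or with like names 13 pairs were left against 7.34 expected (95% range of shuffles 3 to 13, permutation p = 0.035), a smaller excess that stays open. Among the near or like-named pairs, Phf11d, Phf11c, Setdb2 and Cab39l lie in a row, with differences of -1.67, -1.82, -1.82 and -1.77. Cep295nl neighbours Timp2 (-1.78), also a near pair. None of these pairs is among the 13 left. Segregating strain variants cannot be told apart from treatment here: 1 of the 9 other splits also had an excess, but only 1 of them expected 5 or more pairs, so the bound set in advance (fewer than 2 splits) could not decide. No biological explanation was tested.

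The splits bear on the counts as well, and 10 are too few for a share under 0.05. For genes past the adjusted threshold the real split gave 1 and the highest other 0 (1 of 10 splits as large). At an unadjusted p of 0.01 the real split gave 711 and the split of placebo array 1 with RU486 arrays 1 and 3 gave 1291 (2 of 10 as large). For lists past the set test the real split gave 10 and the highest other 18 (6 of 10 as large). The split with 1291 genes held 1260 genes after median centring and 1493 after quantile normalization. A structure of the samples besides treatment may account for it, but this was not told apart from chance.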
